A study of Homo sapiens with 7 samples.

How the data were processed

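The screen used Jurkat cells, an established human T cell leukaemia line, that express the Cas9 nuclease. Per the labels' protocols, the cells were transduced with a lentiviral library of single guide RNAs, each of which directs Cas9 to cut 1 gene. Puromycin selection ran from day 2 to day 5 after transduction. From day 6 the cells grew in 0, 50 or 200 µM paraquat, a redox-cycling herbicide that generates superoxide, for 14 or 21 days, with over 1000 cells per guide throughout. Genomic DNA was taken at the start (day 0) and at the end of exposure. Guide sequences were amplified from 2.5 µg of DNA in 22 PCR cycles and sequenced as single 75-base reads. Each of the 7 conditions has 1 library, and the labels do not say whether the day 14 and day 21 cells came from separate flasks.

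The authors deposited 1 table of raw read counts per guide, with 1 column for each library. Bowtie and the genome build GRCh38 are named in the submitters' processing notes, with no version. How reads were matched to guides and whether mismatches were allowed is not given in the sources used here. No guide sequences or target positions were used, so a guide that also cuts a near-identical gene copy cannot be told from one that does not. After 2350 blank lines were left out, the table held 8260 guides, namely 10 for each of 776 genes and 500 non-targeting guides. Of the gene names, 761 matched a current symbol and 15 an older symbol in the RefSeq table of GRCh38.p14, which also gave the gene positions.

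Total counts ran from 4668327 to 12004564 per library. The median count per guide was between 532 and 1337.5, and 35 guides were at 0 in every library. Guides entered a comparison if their mean count over its libraries was at least 30, which kept 8123 guides for the paraquat comparisons and 8140 for the comparison without paraquat. All 500 non-targeting guides were kept in both. PCR reads carry no molecular identifiers, so intervals from counts cover counting error only.

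For each guide, log2 CPM (counts scaled to a common library size) was computed from the deposited counts, with library sizes from the column totals and a prior count of 5, by the formula of edgeR's cpm function. Log2 ratios were taken within a day and averaged over days 14 and 21. Each day without paraquat was set against day 0, and each dose against the library without paraquat of the same day. A gene's score was the median over its guides minus the median of the non-targeting guides. Folds given for scores are therefore relative to the non-targeting guides. The score was tested 2-sided by permutation against 100000 random sets of as many non-targeting guides, and p was adjusted by the Benjamini-Hochberg method over the 776 genes. The smallest p these draws can give is 1e-05. A gene counted as changed if the adjusted p was under 0.05 and the score had the same sign on both days. The change of the 200 µM effect between the days was tested in the same way on the difference of the log2 ratios, without the rule on signs. Errors beside scores are standard errors over the gene's guides (SD over the square root of their number).

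These p-values compare guides within the sequenced libraries. They are not a test across replicate cultures, because there are none. Single guides were also tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, terms for day 0, day 21, 50 µM and 200 µM, 2 residual degrees of freedom), and DESeq2 1.42.0 was an alternative. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

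Before the data were examined, 23 gene lists, the tests and the first set of alternatives were fixed. Of the lists, 19 had at least 3 genes in the library. A further 5 lists (T cell receptor signalling, apoptosis and cell cycle arrest, RNA polymerase II subunits, nuclear transport, multi-copy gene families) were written after the gene names but before any score was seen. For each list, the genes that passed were counted, and the list median was placed as a percentile among 10000 random lists of the same size matched on mean count. For the comparison without paraquat, lists matched on the day 0 count were used in the text. That choice was made after the data were seen, because the mean count itself falls with depletion.

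The genes named in the text follow a rule fixed at the same time. Without paraquat these were the 15 lowest and up to 10 highest genes that passed. At each dose they were up to 15 per direction, and for the dose and day differences up to 5 per direction. Where fewer than 5 passed in a direction, the 5 most extreme scores were taken. For each list, the 4 members farthest in the direction of its median and any member that passed could be named. Some genes that meet this rule are not reported here.

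The gene test was tested on simulated counts with the real library sizes and guide drift of the size seen among non-targeting guides. For 200 µM against 0 µM over 776 genes, it recovered 100% of 100 genes changed 1.5-fold and 100% of 100 genes changed 2-fold. It called 13 of 576 unchanged genes. The guides of real genes spread more than this drift. Their median SD at 200 µM was 0.33 to 0.55 over groups of genes by depletion, against 0.30 for non-targeting guides. These shares therefore cannot be carried over to the real genes. The edgeR test of 8140 guides for the same comparison recovered 86% of simulated 2-fold and 100% of 4-fold changes, with 6 false calls. In the real data it called 15.6% of the 500 non-targeting guides at 200 µM, so its simulated error does not carry over either. The alternatives for genes were all guides or the germline and neuron guides as null, no filter or a mean count of at least 100, a prior count of 1 or 20, the mean over guides, the median without the strongest guide, each day alone, TMM library sizes, edgeR on counts summed over a gene's guides, and subtraction of a linear fit on depletion without paraquat. For single guides they were DESeq2 size factors, scaling to the non-targeting guides, no filter or the stricter one, DESeq2's Wald test, the 6 late libraries alone and paraquat as 1 term. Lists were also taken without genes of more than 1 list. Added after the data were seen were the matching on day 0 counts, the count per list against germline and neuron guides, and an exact 2-sided sign-flip test of each gene's own guides about the non-targeting median, which uses the spread of that gene's guides.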

Results

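The series asked which RNA binding proteins alter the growth or survival of human T cells under oxidative stress. Jurkat-Cas9 cells carrying a pooled knockout library against RNA binding proteins, with added redox, apoptosis and T cell receptor genes, were sampled at day 0 and after 14 or 21 days in 0, 50 or 200 µM paraquat. Guide abundance was counted in 7 libraries, 1 per condition. A guide becomes rarer if loss of its gene slows or kills the cells, and more frequent if the loss favours them relative to the rest of the pool, but a cut in the DNA can also slow cells whatever the gene.

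The day 0 library held 7014227 counts. At day 14 the totals were 6902069, 4668327 and 7003562 counts at 0, 50 and 200 µM, and at day 21 they were 12004564, 5251017 and 5481116. Between 65 and 95 of the 8260 guides were at 0 in a library. Guides became less even with time, with a Gini index of 0.231 at day 0, from 0.333 to 0.340 at day 14 and from 0.361 to 0.395 at day 21. The non-targeting guides, which cut no gene, rose from 6.46% of the counts at day 0 to between 9.81% and 11.3% in the later libraries.

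Growth without paraquat depleted guides against most of the library. Of 776 genes, 724 were lower than the non-targeting guides after 14 and 21 days, 2 were higher and 50 did not pass. The lowest score, -3.60 on the log2 scale (SE 0.54 over 10 guides) or 0.083-fold relative to the non-targeting guides, belonged to SOD2, the mitochondrial superoxide dismutase (chromosome 6, 159669069 to 159762281, GRCh38). It was followed by the RNA polymerase II subunit POLR2L at -3.51 (SE 0.25), the SF3B component PHF5A at -3.35 (SE 0.25), the spliceosomal ubiquitin ligase PRPF19 at -3.24 (SE 0.25) and POLR2J3 at -3.22. POLR2J3 and POLR2J are near-identical copies, so their scores are uncertain, and 6 guides of POLR2J3 passed the filter. The other genes among the 15 lowest were UBA1, the ubiquitin-activating enzyme, at -3.19, POLR2J at -3.15, the nuclear transport GTPase RAN at -3.13, the glycolytic enzyme GAPDH at -3.11, the initiation factor helicase EIF4A1 at -3.10, the ribosomal protein RACK1 at -3.06, RUVBL1 at -3.04, DHX33 at -2.96, EIF6 at -2.95 and SRSF1 at -2.93. For all 15 the adjusted permutation p was 1.85e-05, the smallest these draws can give after adjustment, and every guide of each gene fell.

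Guides against RBM41 and GCFC2 were higher, at 0.24 (SE 0.16, adjusted permutation p = 0.0117) and 0.21 (SE 0.21, p = 0.0247). Neither passed against all guides as the null, with the mean over guides or by an exact sign-flip test of its own guides. RBM41 also did not pass at day 21 alone, nor GCFC2 without its strongest guide. The next highest scores, of FAM46D at 0.14, RBMY1E at 0.13 and FMR1 at 0.08, did not pass. By list, all 26 core spliceosome genes fell (median -1.83), as did all 36 translation initiation factors (-1.68), all 24 cleavage and polyadenylation genes (-1.57), all 22 mRNA export genes (-1.39) and all 24 mitochondrial gene expression genes (-1.26). The same 26, 36, 24, 22 and 24 passed when adjusted over the list alone. The medians of these lists lay at percentiles 0.21, 0.02, 0.02, 0.68 and 0.82 of random lists matched on the day 0 count, and at 63.0, 27.6, 2.33, 20.7 and 5.91 with the matching on mean count fixed beforehand. The integrated stress response list, whose measured genes are the 5 subunits of the eIF2 exchange factor and 3 eIF2 kinases, had 7 of 8 genes lower and a median of -1.97 (percentile 0.08). Over the 2 genes found in no other list, EIF2AK1 and EIF2AK3, the median was -0.32. SR proteins and hnRNPs fell in 46 of 47 genes, with a median of -0.82 (percentile 30.2), and in 27 of 47 against the germline and neuron guides as null.

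Proteins restricted to the germline or neurons also fell in 48 of 59 genes, with a median of -0.41 (fold 0.753). Against the guides of that list in place of the non-targeting guides, 398 genes were lower and 7 higher. With that null, all 26 core spliceosome genes, 29 of the 36 initiation factors and 18 of the 24 mitochondrial genes were lower. So were 3 of the 59 germline and neuron genes, but their own guides form this null, so few of them could pass. The median score over all genes was -0.73 relative to the non-targeting guides.

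**Figure D1:**
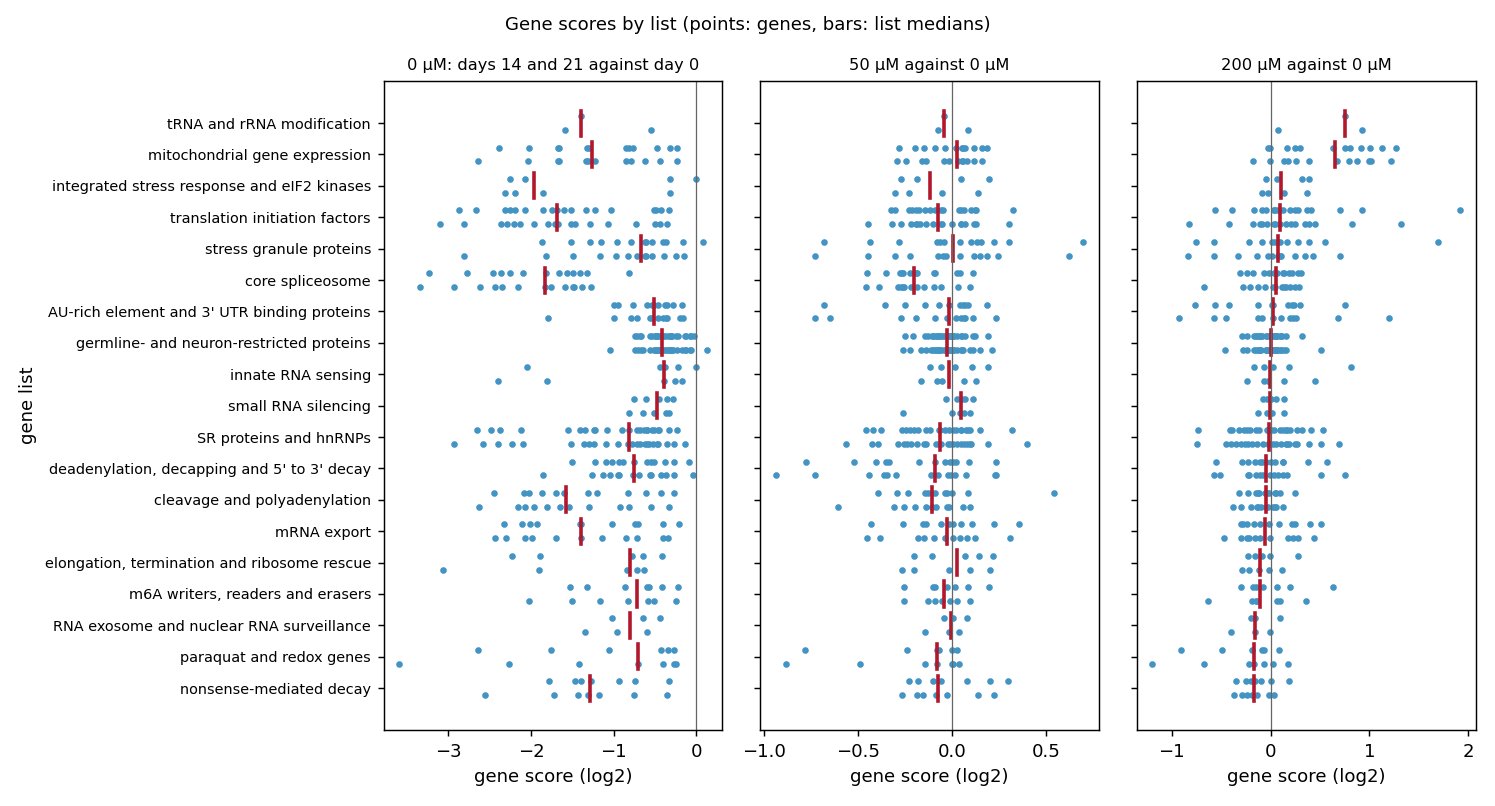
Gene scores (log2, x axis) by gene list (y axis) for growth without paraquat, 50 µM and 200 µM, with genes as points and list medians as bars. The mitochondrial gene expression list has a median of -1.26 without paraquat, 0.03 at 50 µM and 0.65 at 200 µM.

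At 200 µM paraquat, guides against 102 genes were more frequent than without paraquat and guides against 88 genes less frequent, while 586 did not pass. Scores at a dose are relative to 0 µM, so guides that merely fell less than without paraquat also count as higher. Guides against STRAP, a WD-repeat protein (chromosome 12, 15882387 to 15903478), rose 5.94-fold, a score of 2.57 (SE 0.26 over 9 guides), with 2.11 at day 14 and 2.77 at day 21. The initiation factor helicase EIF4A1 (chromosome 17, 7572825 to 7579006), whose guides fell strongly without paraquat, rose 3.78-fold to 1.92 (SE 0.20). The helicase DDX3X stood at 1.69 (SE 0.30) and the initiation scaffold EIF4G1 at 1.32 (SE 0.17). The Pumilio-like protein PUM3 followed at 1.39 (SE 0.20), HDLBP at 1.22 (SE 0.12) and the mRNA-stabilising protein ELAVL1 at 1.20 (SE 0.18).

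Several of the 15 highest genes act in mitochondria. They were the translation elongation factor TUFM at 1.26 (SE 0.30), the RNA phosphorylase PNPT1 at 1.22 (SE 0.20), the 3' exonuclease PDE12 at 1.14 (SE 0.25), the RNA granule protein GRSF1 at 1.13 (SE 0.13), the poly(A) polymerase MTPAP at 1.01 (SE 0.23), the DNA-packaging transcription factor TFAM at 1.00 (SE 0.21) and the mRNA-stabilising LRPPRC at 0.99 (SE 0.15).

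The lowest gene was SOD1, the cytosolic superoxide dismutase (chromosome 21, 31659693 to 31668931), at -1.20 (SE 0.27), or 0.437 of its level without paraquat relative to the non-targeting guides. The helicase DDX5 stood at -1.04 (SE 0.11), SAMD4B, a Smaug-type regulator of mRNA decay, at -0.93 (SE 0.16), and the peroxidase PRDX1 at -0.90 (SE 0.10). Then came EWSR1 at -0.84, the cap-binding EIF4E2 at -0.82, PUM2 at -0.76, the G3BP1-binding deubiquitinase USP10 at -0.76, GAPDH at -0.75, PCBP2 at -0.75, SRSF10 at -0.73, the T cell receptor adaptor LCP2 at -0.69, FUBP1 at -0.68, SF3B5 at -0.68 over 6 guides and the thioredoxin reductase TXNRD1 at -0.67. Each of the 30 extreme genes had an adjusted permutation p of 0.000106, the smallest these draws can give after adjustment.

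**Figure D2:**
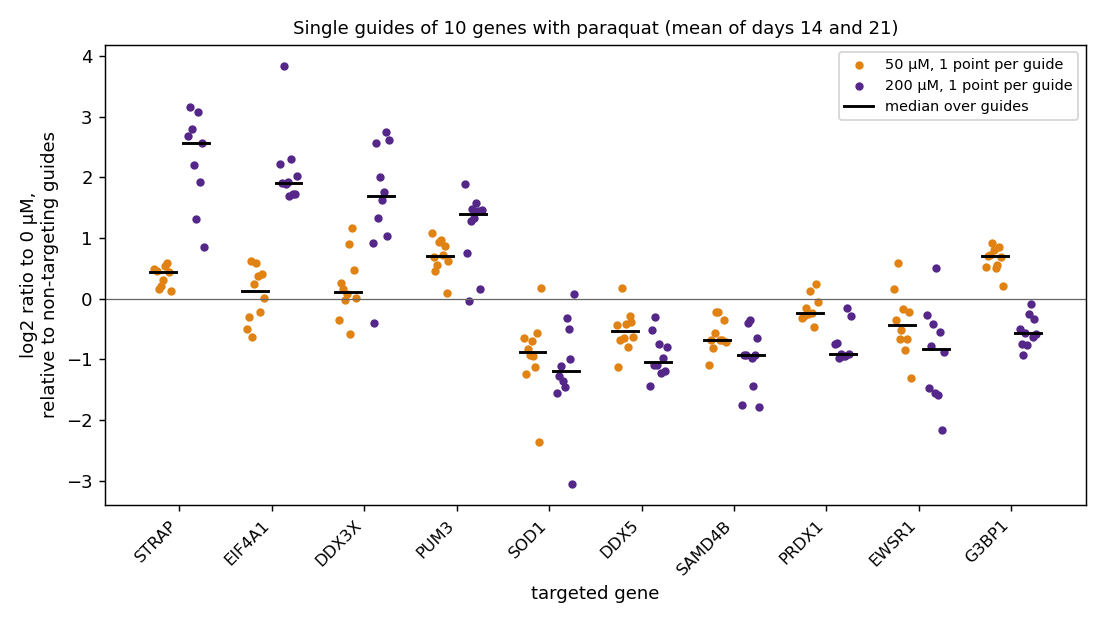
Log2 ratio to 0 µM of single guides (y axis, relative to non-targeting guides) for genes among the 5 highest and the 5 lowest at 200 µM and for G3BP1 (x axis), with 50 µM in orange, 200 µM in purple, a point per guide and medians as black lines. All 9 guides of STRAP lie above 0 at 200 µM, and all 10 guides of G3BP1 lie above 0 at 50 µM and below 0 at 200 µM.

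Of the 24 genes of mitochondrial gene expression, 15 were higher and 0 lower at 200 µM (17 when adjusted over the list alone), and the median of 0.65, a 1.57-fold rise, exceeded all random lists matched on mean count (percentile 100). By the exact sign-flip test of their own guides, 2 of the 15 passed, and all 15 had an unadjusted p under 0.05. The 15 included the RNA polymerase POLRMT at 0.81, the helicase SUPV3L1 at 0.87, the elongation factor GFM1 at 0.91 and FASTKD5 at 0.80. In the list of tRNA and rRNA modification, RPUSD3 at 0.75 and RPUSD4 at 0.93, which are mitochondrial pseudouridine synthases, were higher out of 3 genes (2 when adjusted over the list alone).

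Translation initiation factors had 10 genes higher and 4 lower of 36 (13 and 4 when adjusted over the list alone; median 0.09, percentile 99.1). Among random lists matched on depletion without paraquat the median lay at percentile 96.5, and the exact sign-flip test called 3 higher and 1 lower. Besides EIF4A1 and EIF4G1, the higher ones included EIF4H at 0.93, EIF4E at 0.82 and EIF1AX at 0.71, and the lower ones EIF4E2 and DENR at -0.56. In the list of paraquat and redox genes, 4 of 13 were lower and 0 higher (4 when adjusted over the list alone; median -0.17, percentile 0.535), namely SOD1, PRDX1, TXNRD1 and the mitochondrial peroxidase PRDX3 at -0.49. By the exact sign-flip test of their own guides 0 of these 4 passed, and 3 had an unadjusted p under 0.05. Nonsense-mediated decay had 3 of 14 genes lower, among them UPF3B at -0.35 and UPF3A at -0.29 (3 when adjusted over the list alone; percentile 2.44), of which 0 passed the sign-flip test. Stress granule proteins moved both ways, with 7 of 26 higher and 5 lower (8 and 5 when adjusted over the list alone), among them NUFIP2 at 0.70 and TARDBP at 0.55 against USP10 and SERBP1 at -0.58. Among the 59 germline and neuron genes, 2 were higher and 3 lower (1 and 1 when adjusted over the list alone).

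At 200 µM the non-targeting guides had an SD of 0.30. The genes were split into 5 groups by depletion without paraquat. The guides of a gene had a median SD of 0.55 in the most depleted group and 0.33 in the least depleted. The test is therefore less strict for genes of every group, and least strict for the most depleted. In the most depleted group 55 genes passed it, and 3 of them passed the exact sign-flip test of their own guides. Against all guides as the null, 55 genes were higher and 34 lower, and an exact sign-flip test of each gene's own guides called 24 higher and 10 lower.

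At 50 µM, guides against 38 genes were more frequent and guides against 167 less frequent than without paraquat. PUM3 rose 1.62-fold to 0.70 (SE 0.09), G3BP1, the core protein of stress granules (chromosome 5, 151771954 to 151812785), to 0.70 (SE 0.07), and its interactor NUFIP2 to 0.62 (SE 0.06). The ribosome-associated GTPase DRG1 at 0.55 (SE 0.08), the cleavage factor CPSF7 at 0.54 (SE 0.06), AUH at 0.48, STRAP at 0.45, SRSF5 at 0.40, HDLBP at 0.37, THOC6 at 0.35, ACIN1 at 0.34, EIF4E at 0.32, HNRNPC at 0.32 and NXT1 at 0.31 were also among the 15 highest.

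The lowest gene was PAN3 at -0.94 (SE 0.15), the partner of the deadenylase PAN2, which stood at -0.73 (SE 0.07). SOD1 was at -0.88 (SE 0.20), the paraspeckle protein NONO at -0.79 (SE 0.09), SOD2 at -0.78 (SE 0.25) and CNOT2, a CCR4-NOT subunit, at -0.77 (SE 0.15). The 15 lowest also included TIAL1 at -0.73, the transcription elongation factors SUPT6H at -0.70 and SUPT4H1 at -0.65, SAMD4B at -0.68, TARDBP at -0.68, LUC7L2 at -0.66, POLR2J at -0.61 and CSTF3 at -0.60. The adjusted permutation p was 0.000121, the smallest these draws can give after adjustment, for the 10 highest and the 15 lowest genes, and at most 0.000948 for the others.

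Core spliceosome genes fell at 50 µM in 13 of 26 cases and rose in 0 (median -0.20), with CDC5L at -0.46 and U2AF2 at -0.45, and the count adjusted over the list alone was also 13. By the exact sign-flip test of their own guides 0 of the 13 passed, and 7 had an unadjusted p under 0.05. Deadenylation and decay genes fell in 11 of 27 cases and rose in 2 (11 and 2 when adjusted over the list alone), including CNOT3 at -0.52, CNOT1 at -0.44 and CNOT9 at -0.40. By the sign-flip test 5 of the 11 and 1 of the 2 passed. The medians of both lists lay within those of random lists, at percentiles 17.1 and 15.9. Cleavage and polyadenylation genes were lower in 7 of 24 cases and higher in 1 (7 and 1 when adjusted over the list alone), and translation initiation factors in 9 and 2 of 36 (11 and 2). In these lists 33.3% and 30.6% of genes passed, against 26.4% over all genes. Their medians lay at percentiles 44.9 and 91.8 of random lists, so neither list was low as a whole. By the exact sign-flip test the 1 higher cleavage gene passed, but 0 of the 7 lower ones and 0 of the 9 lower and 2 higher initiation factors, with 7, 2 and 0 at an unadjusted p under 0.05. Paraquat and redox genes were lower in 4 of 13 (percentile 33.3), with TXNRD1 at -0.49 and PRDX1 at -0.24 beside SOD1 and SOD2. Of these 4, 1 passed the exact sign-flip test and 2 had an unadjusted p under 0.05. Of the 24 mitochondrial gene expression genes, 0 were higher and 1, PTCD2 at -0.29, was lower (0 and 1 when adjusted over the list alone). The list median of 0.03 nevertheless lay at percentile 99.6 of random lists matched on mean count.

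At 50 µM the non-targeting guides had an SD of 0.21. The guides of a gene had a median SD of 0.44 in the most depleted of the 5 groups and 0.22 in the least depleted. The test is therefore less strict for the most depleted genes at this dose too. In the most depleted group 74 genes passed it, and 2 of them passed the exact sign-flip test. The 50 µM counts varied more with the method. They were 67 higher and 90 lower after a linear fit on depletion without paraquat was subtracted, 60 and 108 at day 14 alone, 18 and 50 against all guides, 11 and 25 by the exact sign-flip test of a gene's own guides, and 0 and 3 when edgeR tested counts summed over guides.

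**Figure D3:**
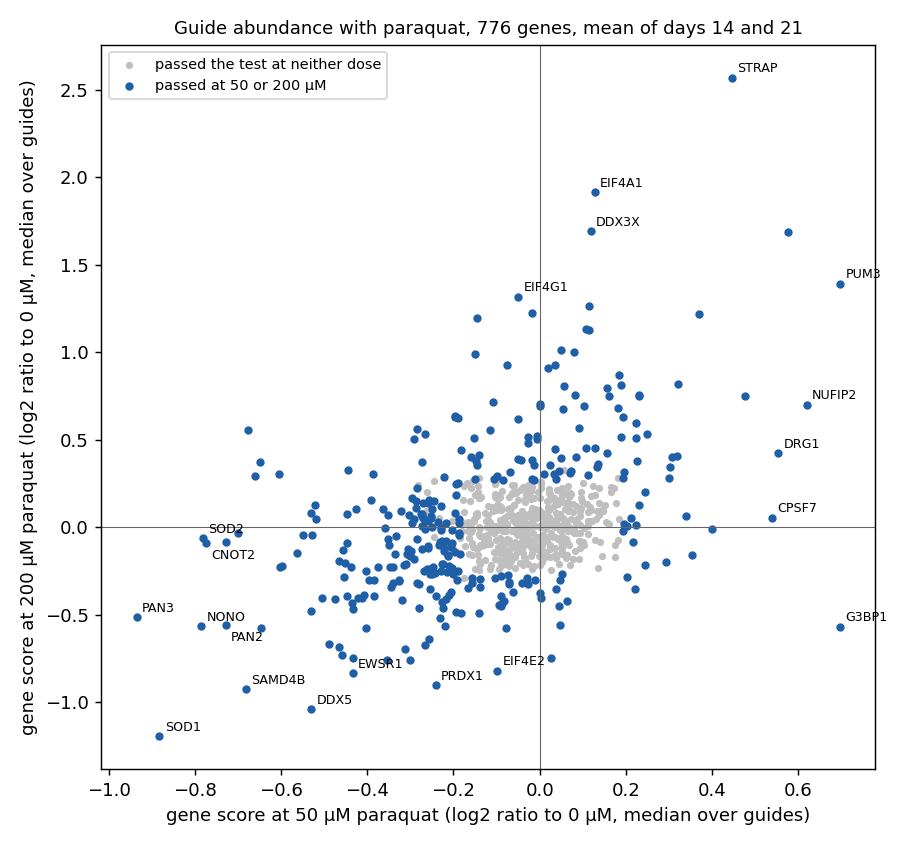
Gene scores at 50 µM (x axis) and 200 µM (y axis), as log2 ratios to 0 µM averaged over both days, with a point per gene, blue where it passed the test at either dose and grey where it passed at neither. STRAP lies at 0.45 and 2.57, SOD1 at -0.88 and -1.20, and G3BP1 at 0.70 and -0.57.

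The direct comparison of the doses found 177 genes higher at 200 than at 50 µM and 48 lower. STRAP at 2.15 (SE 0.24), EIF4A1 at 1.99 (SE 0.20), ELAVL1 at 1.56 (SE 0.19), DDX3X at 1.49 (SE 0.32) and TUFM at 1.20 (SE 0.23) were highest. G3BP1 was lowest at -1.22 (SE 0.12), a fold of 0.429, followed by PCBP2 at -0.87, PRDX1 at -0.64, EWSR1 at -0.57 and SMG9 at -0.53, all with an adjusted permutation p of 0.000111, the smallest these draws can give after adjustment. Of the mitochondrial gene expression list, 17 of 24 genes were higher and 0 lower (19 when adjusted over the list alone; median 0.63, percentile 100). Deadenylation and decay genes were higher in 12 of 27 cases and lower in 1 (percentile 99.8). After the fit on depletion without paraquat was subtracted, 99 genes were higher and 95 lower, and the exact sign-flip test called 56 and 9.

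Both doses shared 22 higher genes, where independent lists of these sizes would share 5.00, and 47 lower genes, where they would share 18.9. The shared higher genes included STRAP, PUM3, HDLBP and NUFIP2, and the shared lower genes SOD1, PRDX1, TXNRD1, SAMD4B, DDX5, PAN2, PAN3 and PUM2. The doses were set against the same untreated libraries. Random sets of 10 non-targeting guides were called higher at both doses in 0% of 10000 sets and lower at both in 0.06%. These sets come from the guides that define the test, and were called in 1.44% at 50 µM and 1.27% at 200 µM. The guides of genes spread more, so the sets cannot exclude that the shared libraries or drift contributed to the overlap. A further 15 genes passed in opposite directions at the doses, G3BP1 and GTPBP1 being higher at 50 µM and lower at 200 µM, and 13 the other way round, where independent lists would share 4.31 and 22.0.

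Between day 14 and day 21 the 200 µM effect became more positive for 52 genes and more negative for 77. These values are medians over guides of the change of each guide, which can differ from the change of the gene's median. EIF4A1 gained 0.83 (SE 0.13), EIF2B1 0.60, ELAVL1 0.58, the eIF2 kinase EIF2AK1 0.57 (SE 0.07) and TARDBP 0.53 (SE 0.09). DDX5 changed by -0.63 (SE 0.08), PRDX1 by -0.62 (SE 0.13), WDR83 by -0.61, HNRNPF by -0.59 and SCAF4 by -0.56. Each had an adjusted permutation p of 0.000204, the smallest these draws can give after adjustment. The exact sign-flip test of a gene's own guides called 0 genes, with 110 at an unadjusted p under 0.05 and a lowest adjusted p of 0.117.

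Across genes, which are not independent replicates, the 200 µM scores of days 14 and 21 correlated at a Pearson r of 0.855 (Spearman 0.730), against 0.639 for random sets of non-targeting guides. At 50 µM the value was 0.517 (Spearman 0.475), against 0.384. Since non-targeting guides also moved alike on both days, the same sign on both days was not an independent check. On the same day, the 50 and 200 µM scores correlated at 0.519 (day 14) and 0.317 (day 21), against 0.336 and 0.232 for non-targeting sets with the same shared library. Their covariances were 0.0231 and 0.0357, against 0.00177 and 0.00325. In the pairings of different days, which share no library, r was 0.398 (50 µM at day 14 with 200 µM at day 21) and 0.262 (the reverse), against 0.226 and 0.227, with covariances of 0.0241 and 0.0217 against 0.00178 and 0.00213. The 200 µM score had a weak relation to depletion without paraquat in the 2 pairings that share no library. Its r was -0.205 and -0.036, against -0.117 and -0.133 for non-targeting sets. The 50 µM score had 0.120 and 0.302, against -0.156 and -0.064.

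For single guides, the edgeR quasi-likelihood test called 980 guides higher and 791 lower at 200 µM, 91 and 66 at 50 µM, and 882 and 735 at 200 against 50 µM. Without paraquat it called 1826 higher and 2013 lower, and scaling to the non-targeting guides turned this split to 202 and 5101. The same scaling turned the split between the doses to 1081 and 500. Of the 500 non-targeting guides, 15.6% were called at 200 µM, 0.6% at 50 µM and 86.8% without paraquat. Under scaling to the non-targeting guides these shares were 15.4%, 0% and 15.6%, so most of the 86.8% came with the TMM scaling. With 50 and 200 µM as 1 term the edgeR test called 0 guides, with 806 at an unadjusted p under 0.05.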

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

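The change of the 200 µM effect between days 14 and 21 was tested itself, by the guide permutation test. It passed for 52 genes in the positive and 77 in the negative direction. The sign-flip test of a gene's own guides was chosen after the data were seen and called 0 of these genes after adjustment, with a lowest adjusted p of 0.117, while 66 of the 129 had an unadjusted p under 0.05. With 10 guides the smallest p it can give is 0.00195.

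Among the genes named at 200 µM or for the change between the days, the median change of a gene's guides from day 14 to day 21, relative to non-targeting guides, was 0.83 for EIF4A1, 0.60 for EIF2B1, 0.58 for ELAVL1, 0.57 for EIF2AK1, 0.53 for TARDBP, 0.50 for PUM3, 0.49 for STRAP, 0.46 for GRSF1, 0.41 for DDX3X, 0.40 for HDLBP, 0.38 for PDE12, 0.32 for TFAM and 0.27 for EIF4G1. All of these but EIF2B1, EIF2AK1 and TARDBP are among the 15 highest genes at 200 µM, which follows from listing named genes only.

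The median change of the guides was -0.63 for DDX5, -0.62 for PRDX1, -0.61 for WDR83, -0.59 for HNRNPF, -0.56 for SCAF4, -0.54 for GAPDH, -0.52 for SRSF10, -0.46 for SF3B5, -0.44 for LCP2, -0.38 for SOD1, -0.34 for TXNRD1, -0.30 for PUM2 and -0.24 for USP10. The change of a gene's median score can differ from these values. The score of HNRNPF, for example, went from -0.41 to -0.60, that of SCAF4 from -0.08 to -0.93, that of WDR83 from 0.56 to 0.18 and that of EIF2B1 from 0.10 to 0.48.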

How the results depend on the processing

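The exact sign-flip test of a gene's own guides was chosen after the data were seen, and the other alternatives compared here before. Of 1340 values of the 100 named results under the alternatives, 1225 kept their direction and their side of the threshold, 108 kept the direction but no longer passed, 7 passed only under the alternative and 0 changed sign. Of the 108, 53 came from the sign-flip test and 34 from edgeR on counts summed over guides. The total includes alternatives that moved nothing, so it overstates how hard the results were tested. TMM library sizes, no filter and a prior count of 1 kept 100 results each, and library scaling all but cancels against the non-targeting median. The sign-flip test kept 47, and the summed counts, which did not cover the change between days, kept 53. Without genes of more than 1 list, the 54 medians of lists left with at least 3 genes stayed within 1 SD of the list's genes. Many of these lists lost no gene, so their medians could not move, and 1 SD is a wide bound. The stress granule median at 50 µM, for example, went from 0.003 to -0.034, within an SD of 0.335. The integrated stress response list, left with 2 genes, was not among them, and its median moved from -1.97 to -0.32 without paraquat, from -0.12 to 0.17 at 50 µM and from 0.10 to 0.23 at 200 µM.

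Counts that moved by over 1.5 times were as follows, and the cause was not tested except where stated. Against all guides as null, whose spread includes the changed genes, the counts higher and lower were 0 and 147 without paraquat, 55 and 34 at 200 µM, 18 and 50 at 50 µM, 51 and 21 between the doses and 15 and 21 between the days. With the germline and neuron guides as null they were 7 and 398 without paraquat, and 32 were higher between the days. Counts summed over guides in edgeR gave 230 and 286 without paraquat (where all 50 sets of non-targeting guides were also called, with a median log2 change of 0.69, since its zero is not the non-targeting guides), 0 and 3 at 50 µM and 82 higher between the doses. Subtracting the fit on depletion gave 67 and 90 at 50 µM and 99 and 95 between the doses. Day 14 alone gave 60 and 108 at 50 µM. The mean over guides gave 0 higher without paraquat and 118 lower between the days, and leaving out the strongest guide gave 1 higher without paraquat. The sign-flip test gave 0 higher without paraquat (638 lower), 24 and 10 at 200 µM, 11 and 25 at 50 µM, 56 and 9 between the doses, and 0 and 0 between the days. Its smallest p with 10 guides, 0.00195, limits it over 776 genes, and 135 of the 190 calls at 200 µM and 136 of the 205 at 50 µM had an unadjusted p under 0.05. For single guides, scaling to the non-targeting guides gave 202 and 5101 without paraquat and 28 and 39 at 50 µM, and 50 and 200 µM as 1 term gave 0 and 0. With the mean over guides the agreement between days was 0.892 at 200 µM and 0.576 at 50 µM.

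No paired analysis was possible because each condition has 1 library and the labels give no replicate numbers, so libraries were matched by day alone. Counting noise of a non-targeting guide's ratio was from 0.052 to 0.063 on the log2 scale against an observed SD of 0.18 to 0.38, so the counting of reads was a small part of the spread. Where the rest arose (growth in culture, sampling of cells or DNA, PCR) was not tested.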

Other observations

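Over all genes, 24.5% passed at 200 µM and 26.4% at 50 µM. In T cell receptor signalling, a list made after the gene names were seen like the others in this paragraph, 4 of 14 genes were lower and 0 higher at 200 µM (percentile 26.0), and 6 were lower and 0 higher at 50 µM (percentile 0.945). By the exact sign-flip test of their own guides 1 of the 4 and 0 of the 6 passed, and 3 and 6 had an unadjusted p under 0.05. LAT at -0.39 and -0.39, LCP2 at -0.69 and -0.31, PLCG1 at -0.43 and -0.23 and ZAP70 at -0.37 and -0.21 passed at 200 and at 50 µM. RNA polymerase II subunits were lower in 6 of 13 cases at 50 µM, with POLR2L at -0.60 (percentile 42.8), and nuclear transport genes in 6 of 21 at 50 µM (percentile 53.3) and 3 of 21 at 200 µM (percentile 15.4), so these list medians lay among those of random lists. In the apoptosis and cell cycle list, the pro-apoptotic BAK1 was higher at 0.28 at 200 µM and 0.19 at 50 µM, and the anti-apoptotic BCL2 lower at -0.39 and -0.21, out of 13 genes. When adjusted over the list alone, BCL2 passed at 200 µM, and BAK1 at neither dose. At each dose 15.4% of this list passed, less than over all genes, and its medians lay at percentiles 20.4 (200 µM) and 65.2 (50 µM). By the exact sign-flip test BCL2 passed at 200 µM, where BAK1 did not reach an unadjusted p under 0.05. Of 18 multi-copy family genes, 9 were lower without paraquat, with a median of -0.19.

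Other lists were fixed earlier. Small RNA silencing had 0 of 10 genes past the test at 200 µM and 1 at 50 µM, and the RNA exosome list 1 of 6 and 0. At 200 µM, m6A genes had 2 of 14 higher (RBM15 at 0.63) and 2 lower (FTO at -0.64), AU-rich element and 3' UTR binding proteins 4 of 23 higher and 6 lower, elongation and ribosome rescue 1 of 10 higher and 1 lower, and innate RNA sensing 2 of 10 higher, among them ILF2 at 0.45.

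Of the tests below, the one on X-linked genes and the one against non-targeting guides of like day 0 count were chosen after results on the same pattern were seen. The others were set after the gene scores but before their own values, and those by day 0 count were added once the count filter had turned out to remove next to no guides. The rules that a filter removing almost nothing, or an interval spanning the bound of 60%, decides nothing were set after the values were seen, as was the rule that choosing guides on day 0 counts decides nothing for a ratio to day 0.

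The rise of mitochondrial gene expression genes at 200 µM was set against technical explanations. If the treated culture had only passed fewer doublings, the list would lie among random lists matched on depletion without paraquat, but it lay at percentile 100, with 0.65 against a random median of 0.01. Outgrowth of a few guides would leave few guides moved. Of its 235 guides, 80.9% lay above the non-targeting median (95% Wilson interval 75.3% to 85.4%, with guides taken as independent). Scores are medians over guides, so a raised list median already implies a high share, and the share is no separate support. Over each gene's guides with the higher day 0 counts the list median was 0.967 of its main value, which argues against counting noise. The count filter of 100 removed 1 guide and left the ratio at 1, so it says nothing. The rise of 0.65 is smaller than the list's fall without paraquat (median -1.26 against day 0). As a list, these guides were therefore less depleted at 200 µM, not enriched since day 0. That loss of mitochondrial gene expression costs cells less in paraquat than without it is a hypothesis, which repeat cultures with single knockouts would test. No mechanism was tested here. By contrast, the translation initiation factors lay at percentile 96.5 under the same matching, so fewer doublings remain an open explanation for that list's median.

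Guides against germline and neuron genes fell relative to non-targeting guides without paraquat, with a median of -0.41. Relative to non-targeting guides in the same bin of day 0 counts (10 bins), which carry the same counting noise, the list median was 0.937 of its main value (95% interval over resampled genes 0.893 to 1.12), which argues against counting noise. The earlier tests of it decide nothing: the guides with the higher day 0 counts gave 1.10 times the list median (-0.45, against -0.26 for the others), but day 0 is the denominator of this ratio, and the count filter of 100 removed 0 guides and left the ratio at 1. DNA cutting itself is a candidate explanation, as non-targeting guides cut nothing. Members on chromosome X lay 0.14 above autosomal members (permutation test, p = 0.110, 4 against 47 genes). The 8 members on chromosome Y had a median of -0.08, with 1 lower, against -0.43 and 44 of 47 on autosomes, but the copy number of these targets in the line was not analysed here, so the explanation stays open. No biological explanation was tested.

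The 15 genes that passed in opposite directions at 50 and 200 µM were 1.93% of genes, and of 10000 random non-targeting sets 0% did so, but independent lists of these sizes would share more (4.31 and 22.0 genes, against 2 and 13). The 0% cannot exclude drift of guides within the cultures, because these genes' guides had a median SD of 0.45 at 200 µM against 0.30 for non-targeting guides. Of their 148 guides, 64.9% lay in the gene's direction at both doses (95% Wilson interval 56.9% to 72.1%, with guides taken as independent). Outgrowth of a few guides may therefore still contribute. By the exact sign-flip test, 1 gene, G3BP1, passed at both doses, with all 10 guides in opposite directions. The difference between the doses passed for 10 of the 15, but the same guides had selected these genes for opposite calls, so this is no independent support. A dose-dependent role of G3BP1 is a hypothesis for repeat cultures.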
